A study of Mus musculus with 2 samples.

How the data were processed

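Gene expression was measured on 2 two-colour oligonucleotide arrays. Each array compared total RNA of lineage-negative erythroid progenitors from C57BL/6 mouse fetal liver at embryonic day 14.5, transduced with ESlncRNA or with the vector and sorted for GFP. On both arrays the ESlncRNA RNA carried Cy5 and the vector RNA carried Cy3, per the labels, so there was no dye swap and a dye effect of a probe adds to its ratio on both arrays alike. The RNA was amplified and labelled with the QuickAmp kit per the labels' protocols, which give an input of 100 ng for replicate 2.

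The scans were quantified with Feature Extraction 10.1.1.1, per the file headers. The authors' deposited spot values used here are intensities, namely the mean signal of a spot and the median local background in each channel, uncorrected. Feature Extraction's processed intensities, background-subtracted and dye-normalized per the file headers, served as an alternative. The deposited log10 ratios of Cy5 over Cy3 were used only as a check of direction, and they correlated at r = 0.986 and 0.992 with the ratio of the processed intensities on the arrays of replicates 1 and 2. The authors also deposited 1 log2 value per probe and array, made with limma (version not given) per the submitters' processing notes. These log2 values had medians of -0.02 and -0.01. They correlated at r = 0.99997 and 0.99998 with log2 ratios of Cy5 over Cy3 made here by loess on signals without background subtraction, with a median absolute difference of 0.00296 and 0.00287. Their scale and direction were taken from that comparison.

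Here the background was corrected with normexp (offset 50) and each array was normalized with loess, with control spots and spots marked as outliers at weight 0, in R 4.3.3 with limma 3.58.1. Marked spots numbered 284 and 308 of 59305 non-control spots, and 0 spots were saturated. Spots of a probe were averaged. Probes well above background in at least 1 channel on both arrays were kept, 26791 of 55681. They stood for 19871 genes or lincRNA intervals, each represented by its probe with the highest mean intensity. Of the 4885 genes with several probes kept, 269 had called probes of opposite sign. Of the array's probes, 26413 were named by accession through the RefSeq table of assembly GRCm38.p6, 3859 by symbol and 735 by an older symbol, and 24674 kept the name in the file, among them most of the 16251 lincRNA probes. All coordinates are those of the array files, on mm9.

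A linear model with an intercept was fitted with limma (1 residual and 5.27 prior degrees of freedom). P-values were adjusted with Benjamini-Hochberg over all probes kept, and 0.05 was the threshold. A rule of size, at least 2-fold on both arrays, was given beside it. The 27 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. With an estimated correlation camera has only the 1 residual degree of freedom. It then has little power, and a list that does not pass it is not argued against. Groups, the tests of the comparisons, gene lists and alternatives were fixed before the data were examined, except for those said to have been chosen later. So was the rule for named genes: ESlncRNA, the 12 higher and 12 lower genes of largest mean log2 ratio that passed the threshold with 1 sign on both arrays, the 4 members of each list with the smallest p, Pycard, and 3 housekeeping genes. Genes outside that rule are marked where they occur. Where a probe was not well above background in a channel on either array, the fold is a bound written "at least". It sets the mean of the bright channel against the higher of the dim signal and the lowest signal well above background, after loess and Aquantile, and is open to dye bias.

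The median spot signal was 35.9 (vector) and 67.8 (ESlncRNA) on the array of replicate 1, and 39.5 and 76.3 on that of replicate 2. Well above background were 52.1% and 45.6% of the spots on the first and 49.1% and 44.4% on the second. Spike-in controls gave a slope of observed on expected log ratio of 0.948 and 0.940, per the file headers. Both arrays lay on 1 slide and were scanned together, so slide and scan could not be tested as batches. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures or animals. For 101 probes with 10 unmarked spots on each array, the median difference between arrays was 0.0249 on the log2 scale, and the spread between spots of 1 array alone gives 0.0240. In a two-sided permutation test per probe, 7 had p under 0.05 where chance gives 5.05, and 1 passed Benjamini-Hochberg adjustment. The p-values therefore measure the spread between 2 arrays, which may be technical, and each condition may stand for 1 RNA sample.

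The steps were tested on simulated arrays for the comparison of ESlncRNA with vector, with 26791 probes tested and 50 changed at each size. The fit recovered 20% of the changes of 0.25 on the log2 scale, 96% of those of 0.5 and 100% of those of 1 and 2 under a gentle dye curve. Of its 176 calls, 18 were false (10.2%). Under a steeper dye curve 30 of 186 calls were false (16.1%). Both shares lie above the nominal rate. The gentle curve was added after the steeper one had been run. The largest false value was 0.63, and 0 false calls reached 2-fold. Small changes past the threshold can therefore be remains of a dye curve that both arrays share. The simulated changes were few, with as many higher as lower. In the data 120 genes were at least 2-fold higher on both arrays and 1610 lower. The simulation therefore cannot tell how loess treats such an imbalance, also for changes of 2-fold or more. Its dye effect was a curve over intensity only. Dye bias of single probes, which adds to both arrays alike, was not simulated, so its false calls leave out that source at any size.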

Results

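ESlncRNA (also known as lincRNA-EPS) is a long noncoding RNA of erythroid cells, and the series asked what its over-expression did to the transcripts of fetal liver erythroid progenitors. The 2 arrays each gave 1 ratio of ESlncRNA over vector per probe. All values below are log2 ratios of that direction, as the mean of 2 arrays (SD, n = 2 arrays). Over 101 probes with repeated spots, probe means differed between the arrays by about as much as the noise between spots alone gives.

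The first question was whether the over-expressed RNA was seen. No probe carried the accession in the series title, so the lincRNA interval on chromosome 4 from 109071198 to 109078776 (mm9, forward strand) was used, which lies between the probes of Eps15 and Ttc39a. The match rests on those neighbours, which flank this lncRNA in the RefSeq table, and was made after the files were seen. Its brightest probe, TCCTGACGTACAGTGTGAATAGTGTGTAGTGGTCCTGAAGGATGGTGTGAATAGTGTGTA at 109076298 to 109076357, rose by 2.21 ± 0.024 (adjusted p = 2.16e-07). The vector channel was not well above background there, so the RNA was at least 4.62-fold higher. Of the 10 probes of the interval and its shorter form, which ends at 109078714, 8 rose, with bounds from at least 1.53-fold to at least 4.62-fold. The 5 probes of the longer interval, among them the brightest, hold copies of 1 repeated sequence. They may share signal and are not separate measurements. The other probes that rose, of different sequence, gave at least 2.33-fold, 1.83-fold and 1.53-fold. The probe starting at 109077962 did not pass (0.05 ± 0.10, adjusted p = 0.484). The probe starting at 109078212 was not well above background in any channel.

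**Figure D1:**
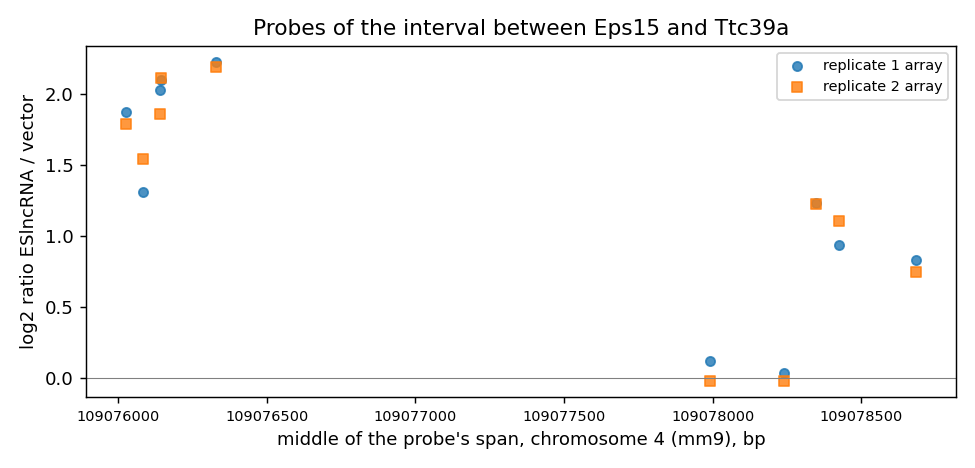
Log2 ratio of ESlncRNA over vector (y axis) for the 10 probes of the interval by position on chromosome 4 (x axis, mm9, bp), with circles for the replicate 1 array and squares for the replicate 2 array. The probe at 109076298 reaches 2.22 and 2.19, and the probes at 109077962 and 109078212 lie near 0.

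Genes of granulocytes were among the 12 most strongly lowered when ESlncRNA was over-expressed. S100a8 and S100a9, the calprotectin subunits of neutrophils, were 43.0-fold and 38.1-fold lower (-5.43 ± 0.028 and -5.25 ± 0.021). Chil3, a secreted chitinase-like protein of myeloid cells, was 44.8-fold lower, and Ctsg, cathepsin G of neutrophil granules, 37.9-fold lower. Plac8 was 37.6-fold lower. The other 7 of the 12 most lowered named genes were members of the stefin A and cystatin cluster on chromosome 16, from Stfa3 at -5.36 ± 0.049 to Stfa2 at -5.81 ± 0.17. These 7 genes are close copies, so their probes may share signal and the separate values are uncertain.

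The genes that rose did so by smaller factors. Aldh1a7, an aldehyde dehydrogenase close in sequence to Aldh1a1, was 4.98-fold higher (2.32 ± 0.0084) and Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, 4.89-fold higher (2.29 ± 0.077). Redrum, a long noncoding RNA of red cells, was 4.09-fold higher. Trib3, a pseudokinase induced by amino acid stress, was 3.75-fold higher and Aqp3, a water and glycerol channel, 3.30-fold higher. The others among the 12 were Sh2d4a (2.11), Tlcd4 (1.96), Btnl10 (1.89), Hesx1 (1.85), St3gal6 (1.78), Prelid3a (1.78) and Pdia2 (1.77).

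Across the 19871 genes tested, 5224 rose and 7306 fell (limma, adjusted p under 0.05), and 7341 did not pass. Of the genes that passed, 8866 changed by less than 1.5-fold. By the rule of size, 120 genes were at least 2-fold higher on both arrays and 1610 at least 2-fold lower, where independent arrays would give 1.24 and 146. The arrays share 1 dye orientation and may hold the same RNA, so an excess over those 2 numbers decides nothing. With median centring 1266 genes were at least 2-fold higher on both arrays and 1175 at least 2-fold lower. At least 4-fold lower on both arrays were 558 genes, and 4 were at least 4-fold higher, among them the ESlncRNA interval itself. Both that interval and its shorter form are counted in the 120 genes at least 2-fold higher. The arrays' log2 ratios had a Pearson r of 0.983 and a Spearman rho of 0.934 across genes, which are not independent replicates. With median centring in place of loess 12511 genes rose and 3634 fell, with Agilent's processed signals 6818 and 4701, so the balance of higher and lower genes rests on the normalization. The share of higher genes among calls was 41.7% with loess, 77.5% with median centring and 59.2% with the processed signals.

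**Figure D2:**
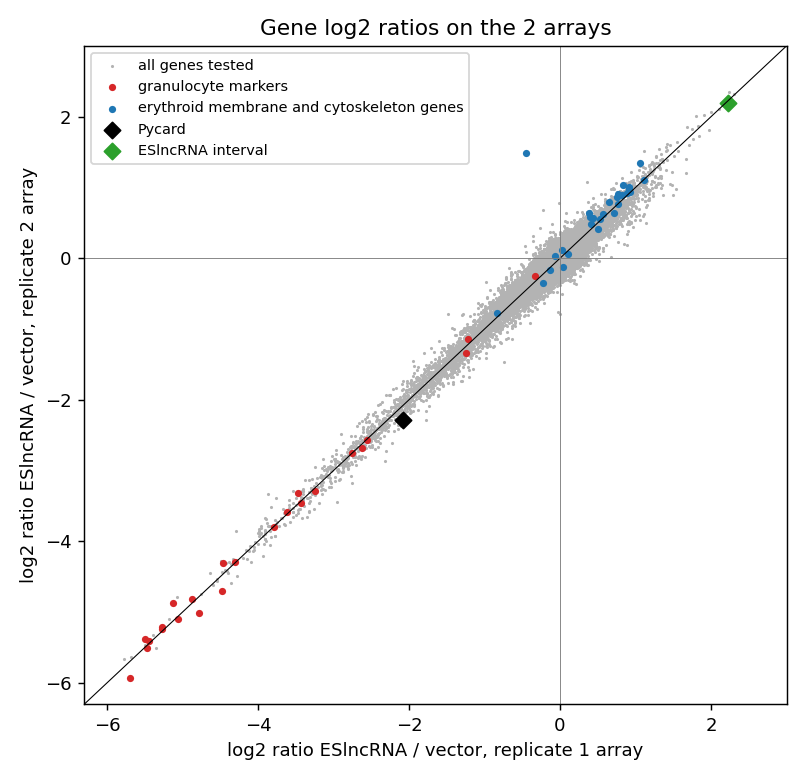
Log2 ratio of ESlncRNA over vector of each gene tested on the replicate 1 array (x axis) and the replicate 2 array (y axis), with granulocyte markers in red, erythroid membrane and cytoskeleton genes in blue, and Pycard and the ESlncRNA interval as diamonds. The line marks equal values, Pycard lies at -2.08 and -2.28, and the blue point far from the line is Slc4a1 at -0.45 and 1.48.

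Markers of other cell types were used to ask what else changed in the sorted population. All 24 granulocyte markers measured fell, with a median of -4.34. Of 25 macrophage markers, 23 fell and 2 rose (median -1.84), with Fcgr3, an IgG receptor, 15.3-fold lower and Csf1r, the receptor of macrophage colony-stimulating factor, 9.90-fold lower. Of 17 mast cell, basophil and eosinophil markers, 16 fell and 1 rose (median -1.999). Cpa3, the mast cell carboxypeptidase, was 20.8-fold lower, Ear2 20.2-fold lower and Ear1 at least 9.98-fold lower. Of 28 megakaryocyte and platelet markers, 26 fell, 1 rose and 1 did not pass (median -1.42), with Plek 6.31-fold and Itgb3, the platelet integrin chain, 5.34-fold lower. Counts adjusted over the list alone were the same in these 4 lists. With no filter on background, which adds dim members, the macrophage median was -1.01 and the mast cell median -1.07, while with Agilent's processed signals the latter was -3.06. Camera gave adjusted p = 4.78e-14 for the granulocyte, 3.31e-08 for the macrophage, 2.35e-07 for the mast cell and 8.85e-09 for the megakaryocyte list. With an estimated correlation the adjusted p = 0.390 for each.

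Endothelial and stromal markers fell too, 25 of 28 (26 adjusted over the list alone), with 3 not passing and a median of -1.07 (camera adjusted p = 3.31e-08, adjusted p = 0.390 with an estimated correlation). Sparc, a matrix protein, was 8.42-fold lower and Col4a1, a basement membrane collagen, at least 5.76-fold lower. With the members not well above background at their bounds, the endothelial and stromal median was -0.93, while it was -2.35 with Agilent's processed signals and -1.81 with a normexp offset of 0. Of 22 hepatocyte markers, 16 fell, 4 rose and 2 did not pass, alike over the list alone (median -0.72, camera adjusted p = 0.00446, adjusted p = 0.390 with an estimated correlation). Trf, transferrin, was 7.54-fold lower and Afp, alpha-fetoprotein, 3.11-fold lower. The hepatocyte median was -0.18 with no filter on background, -1.25 with the processed signals and -1.15 with offset 0. Of 14 lymphocyte markers, 8 fell, 3 rose and 3 did not pass, and the list did not pass (median -0.26, camera adjusted p = 0.142). It passed with median centring (adjusted p = 0.00919, median -0.19) and with the processed signals (adjusted p = 0.0441, median -0.80). The lymphocyte median was -0.02 with no filter on background (adjusted p = 0.284), -0.13 with both channels above background (adjusted p = 0.522) and -0.55 with offset 0 (adjusted p = 0.120), and in fry the list moved down (adjusted p = 0.0148). Cd79b, of the B cell receptor, was 11.6-fold lower.

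Genes of haematopoietic stem cells and early progenitors were lower with ESlncRNA. Of 30 measured, 26 fell, 3 rose and 1 did not pass, alike over the list alone (median -1.50, camera adjusted p = 2.35e-07, adjusted p = 0.390 with an estimated correlation). Cd34, a surface marker of early progenitors, was 18.6-fold lower (-4.22 ± 0.026). Meis1, a homeobox factor of stem cells, was 8.11-fold lower, Cd48 7.55-fold lower and Mycn 5.71-fold lower.

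Erythroid genes rose by modest factors. Of 28 erythroid membrane and cytoskeleton genes, 20 rose, 3 fell and 5 did not pass (median 0.57), among them Ackr1, the Duffy antigen, 2.16-fold higher, Ermap 1.92-fold and Rhag, the Rh-associated glycoprotein, 1.88-fold. Slc4a1, the anion exchanger band 3, was singled out after its values were seen, since its arrays gave -0.45 and 1.48 (mean 0.52, adjusted p = 0.288). Of 34 heme and iron genes, 23 rose, 5 fell and 6 did not pass (median 0.43). Cpox, an enzyme of heme synthesis, was 2.44-fold higher, while Alas1, the housekeeping form of the first enzyme, was 3.84-fold lower and Hmox1, which degrades heme, 2.61-fold lower. Of 33 late erythroid differentiation genes, 22 rose, 6 fell and 5 did not pass (median 0.44), with Hebp1 2.92-fold and Car2, carbonic anhydrase, 2.02-fold higher and Pim1, a kinase, 1.84-fold lower. Of 7 globin genes, 4 rose and 3 did not pass (median 0.43), with Hba-a2 2.03-fold higher and Ahsp, the alpha globin chaperone, 1.85-fold higher. Over the lists alone the rises numbered 20, 24, 23 and 4. Camera gave adjusted p = 4.67e-07, 1.06e-05, 1.55e-05 and 0.0132 for the 4 lists in that order. With an estimated correlation these were adjusted p = 0.427, 0.390, 0.390 and 0.496. With Agilent's processed signals the globin list did not pass (adjusted p = 0.0888), nor did it in fry (adjusted p = 0.120). The globin median was 0.26 with no filter on background. With median centring the 4 medians were 1.26, 1.15, 1.17 and 0.88, against a median of all genes of 0.34. Bright genes of other kinds rose as well, with a ribosomal protein median of 0.36 and Actb at 0.40. With median centring these 2 values were 1.49 and 1.54. With the processed signals they were 0.04 and -0.0013, and the 4 erythroid medians 0.85, 0.54, 0.45 and 0.51. Whether erythroid genes rose more than other bright genes therefore depends on the normalization.

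Erythroid transcription factors and receptors moved both ways, with 16 of 28 higher (17 over the list alone), 6 lower and 6 not passing (median 0.18, camera adjusted p = 0.00725, adjusted p = 0.496 with an estimated correlation). Gfi1b, a repressor of erythroid and megakaryocyte cells, was 1.99-fold higher and Klf1, the activator of adult beta globin, 1.82-fold higher. Id1, an inhibitor of helix-loop-helix factors, was 5.48-fold lower. In fry the list did not pass (adjusted p = 0.120), and its median was 0.33 with the processed signals and 0.74 with median centring. Lyl1 was 1.67-fold lower with loess but at 0.15 with median centring.

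Pycard, the inflammasome adaptor ASC and the gene named in published work on this lncRNA, was 4.53-fold lower (-2.18 ± 0.15, adjusted p = 6.75e-07; NM_023258, probe on chromosome 7 from 135136241 to 135136300). It belongs to the pro-apoptotic and the inflammasome lists. Of 27 inflammasome and inflammatory cytokine genes, 23 fell (24 over the list alone), 1 rose and 3 did not pass (median -1.57, camera adjusted p = 9.33e-08, adjusted p = 0.427 with an estimated correlation). Casp1, the protease that cuts interleukin-1 beta, was 10.5-fold lower, Ccl9 14.7-fold lower, Tlr2, a receptor of bacterial lipoproteins, 8.57-fold lower and Mefv, which encodes pyrin, at least 5.92-fold lower. The inflammasome median was -2.76 with the processed signals and -2.36 with offset 0. The pan-leukocyte genes, a panel of 20 chosen after the arrays had been examined, all fell too, with a median of -2.19.

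The pro-apoptotic and anti-apoptotic lists both missed the threshold of camera, which compares a list with other genes, and passed fry, which tests it against no change. Of 40 pro-apoptotic genes, 25 fell, 9 rose and 6 did not pass (median -0.21, camera adjusted p = 0.0781), and over the list alone 25 fell and 10 rose. Besides Casp1, the members with the smallest p were Tnfrsf1a, a receptor of tumour necrosis factor, 8.45-fold lower, Perp 6.63-fold lower and Pmaip1, the BH3-only protein Noxa, 4.03-fold lower. Of 23 anti-apoptotic genes, 15 fell, 5 rose and 3 did not pass, alike over the list alone (median -0.36, camera adjusted p = 0.0542), with Naip2 3.04-fold and Bcl2 2.10-fold lower. In fry both lists moved down (adjusted p = 0.00748 and 0.0146). Camera passed both with Agilent's processed signals (adjusted p = 0.0498 and 0.0497) and with no filter on background (adjusted p = 0.00166 and 0.00214), and the anti-apoptotic list without the replicate block (adjusted p = 0.0423). With the processed signals the medians of the 2 lists were -0.07 and -0.22, against a median of all genes of 0.11. Relative to all genes they were -0.18 and -0.34, and -0.18 and -0.33 with the main settings. With median centring the medians of these 2 lists lay at 0.36 and 0.14, against a median of all genes of 0.34. Of 23 p53 targets, 12 fell, 4 rose (5 over the list alone) and 7 did not pass (median -0.15, camera adjusted p = 0.308), and Tigar, a regulator of sugar metabolism, was 3.79-fold lower. In fry the p53 list moved down (adjusted p = 0.0148). The p53 median was -0.04 with the processed signals, where that of all genes was 0.11, and -0.06 with no filter on background.

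Several lists on signalling and growth moved as well. Of 39 interferon-stimulated genes, 27 fell, 7 rose and 5 did not pass, alike over the list alone (median -0.76, camera adjusted p = 6.92e-04, adjusted p = 0.390 with an estimated correlation), with Ifitm1 10.5-fold and the transcription factor Irf1 7.57-fold lower. Macrophage markers and the pan-leukocyte panel, with medians of -1.84 and -2.19, were lower in the same RNA as the interferon and immediate early lists. The interferon median was -0.37 with no filter on background and -0.36 with median centring. Of 27 immediate early genes, 23 fell, 2 rose (3 over the list alone) and 2 did not pass (median -0.92, camera adjusted p = 1.25e-05, adjusted p = 0.390 with an estimated correlation), with Fosl2 4.49-fold and Dusp2, a MAP kinase phosphatase, 3.69-fold lower. The immediate early median was -0.55 with median centring, which moved the median of all genes to 0.34. Relative to all genes it was -0.89 with loess and with median centring, and the interferon median was -0.73 and -0.70. Of 58 cell cycle genes, 31 rose, 5 fell and 22 did not pass, alike over the list alone (median 0.16, camera adjusted p = 4.15e-05, adjusted p = 0.390 with an estimated correlation), with Ccne1, cyclin E1, 1.91-fold higher. Of 24 sterol synthesis genes, 18 rose, 1 fell and 5 did not pass, alike over the list alone (median 0.27, camera adjusted p = 1.03e-05, adjusted p = 0.390 with an estimated correlation), with Pmvk, phosphomevalonate kinase, 1.93-fold higher. Of 48 cytosolic ribosomal protein genes, 36 rose (39 over the list alone), 2 fell and 10 did not pass (median 0.36, camera adjusted p = 8.85e-09, adjusted p = 0.496 with an estimated correlation). With median centring the cell cycle, sterol and ribosomal medians were 0.79, 0.91 and 1.49, against 0.34 for all genes. With Agilent's processed signals the ribosomal median was 0.04 and the list did not pass (adjusted p = 0.823), nor did it in fry (adjusted p = 0.0847). The cell cycle and sterol medians were 0.24 and 0.44 with the processed signals. With the mean of a gene's probes the ribosomal median was 0.23.

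The remaining lists did not pass camera with the main settings. Of 30 unfolded protein and amino acid stress genes, 18 fell and 8 rose (median -0.46, camera adjusted p = 0.0857), with Asns, asparagine synthetase, 2.46-fold higher and Calr, a chaperone of the endoplasmic reticulum, 2.59-fold lower. Of 31 glycolysis and hypoxia genes, 14 fell and 9 rose (median -0.10, camera adjusted p = 0.314), with Pfkfb3 4.34-fold lower and Pkm, pyruvate kinase, 3.20-fold lower. Of 17 cell cycle inhibitors, 8 fell and 5 rose (camera adjusted p = 0.930), with Gadd45b 4.02-fold lower and Cdkn1c, which encodes p57, 1.86-fold higher. Of 28 autophagy genes, 13 fell and 4 rose (camera adjusted p = 0.280), with Atg12 1.95-fold lower. Of 13 genes near the ESlncRNA locus, 5 rose and 3 fell (median -0.07, mean 0.01, camera adjusted p = 0.445), with Eps15 1.56-fold higher and Txndc12 1.96-fold lower. Their median was 0.05 on the replicate 1 array and -0.07 on the replicate 2 array, so its sign is not settled. Over these lists alone, in the order given, 19, 14, 8, 13 and 4 fell and 8, 9, 5, 4 and 6 rose. In fry the unfolded protein, glycolysis and autophagy lists moved down (adjusted p = 0.0273, 0.0181 and 0.0444). The unfolded protein list passed camera with the processed signals (adjusted p = 0.0341) and with no filter on background (adjusted p = 0.00408), and with no filter so did the glycolysis and autophagy lists (adjusted p = 0.0392 and 0.0498). With median centring the medians of these 5 lists lay at 0.10, 0.36, 0.46, 0.32 and 0.21, and that of the p53 targets at 0.45, against 0.34 for all genes. Relative to all genes they were -0.24, 0.02, 0.12, -0.02 and -0.13, and 0.11 for the p53 targets.

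The housekeeping genes Actb, Gapdh and Hprt were at 0.40 ± 0.043, 0.31 ± 0.11 and 0.22 ± 0.032, but with Agilent's processed signals Actb and Gapdh lay at -0.0013 and -0.063 and did not pass. Actb, Gapdh and Hprt lay at 1.54, 1.42 and 1.097 with median centring, which moved the median of all genes to 0.34. The size of these changes therefore depends on the normalization. Hprt did not pass with offset 0 (adjusted p = 0.0501) or without the replicate block (adjusted p = 0.0594). Of the 7 probes of Gapdh that were kept, 3 passed in the opposite direction.

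**Figure D3:**
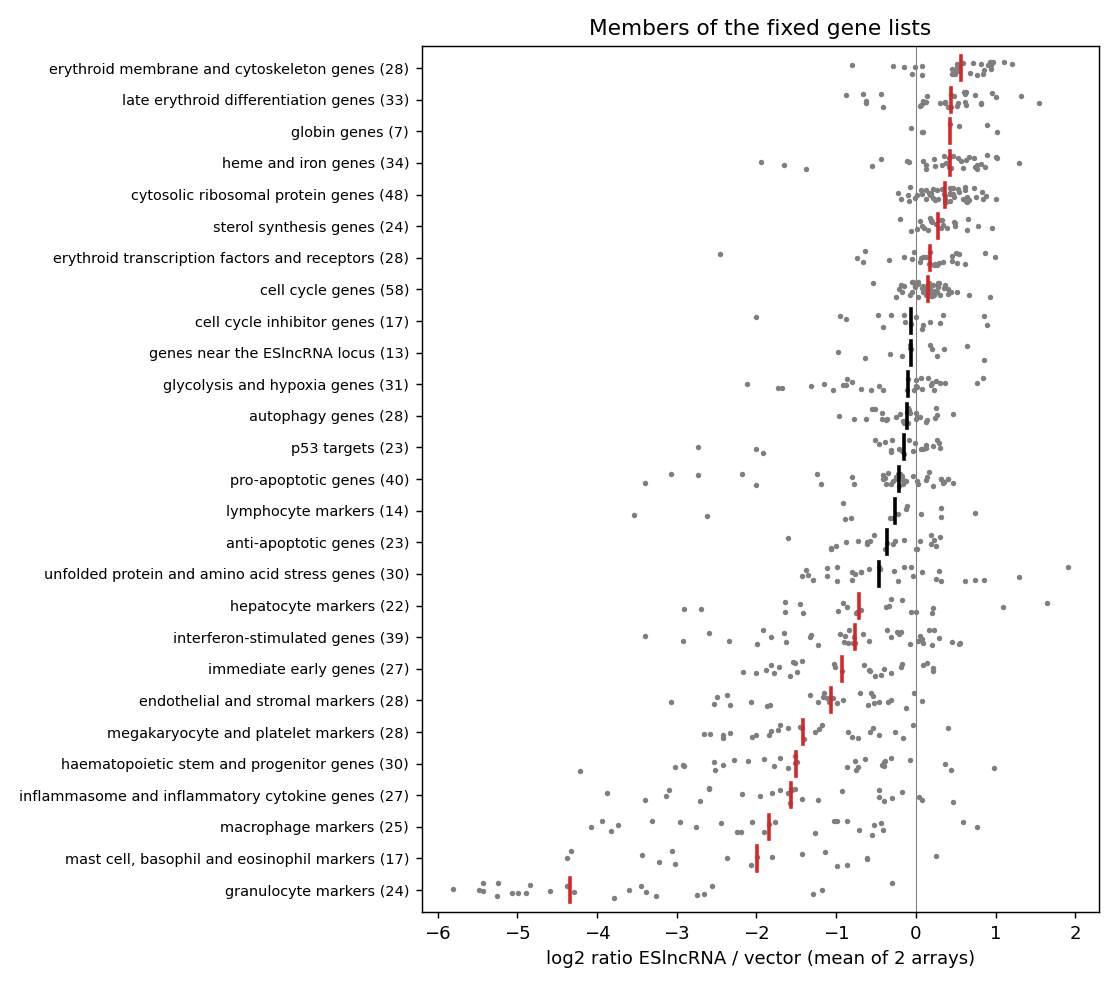
Log2 ratio of ESlncRNA over vector (x axis, mean of 2 arrays) of each measured member (grey points) of the 27 fixed lists, with the number of members in brackets and the median as a bar, red where camera passed with the preset correlation. The granulocyte markers have the lowest median (-4.34) and the erythroid membrane and cytoskeleton genes the highest (0.57), while with median centring the ribosomal protein genes have the highest (1.49).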

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

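The base composition correction was chosen after seeing the data. ESlncRNA stayed higher under each setting that gave a value, from 1.90 to 5.50, and from 2.19 to 2.22 without 1 of the replicates. It had no value where both channels had to be above background. Without 1 of the replicates 1 array was left, which gives values but no test: genes at least 2-fold higher then numbered 147 to 167 and lower 1689 to 1721. Median centring moved the median of all genes from -0.03 to 0.34 and the processed signals to 0.11, so the direction of small changes and the balance of higher and lower genes depend on the normalization. With median centring 12511 genes rose, 3634 fell, 1266 were at least 2-fold higher and 1175 lower. With the processed signals 4701 fell, 708 were at least 2-fold higher and 2455 lower. At least 2-fold higher were 202 genes without background subtraction, 367 with offset 0 and 204 in the deposited log2 values. Without the replicate block, with the 4 channels as separate samples, 3447 genes rose. The correlation between arrays was 0.979 without background subtraction, 0.968 with offset 0, 0.955 with the processed signals, 0.968 with no filter, 0.986 above background in both channels and 0.979 in the deposited values. With an estimated inter-gene correlation 0 of the 27 lists passed (0 had an unadjusted p under 0.05), with fry 22, and with camera at the preset correlation 18, of which 15 passed both. The estimated correlation leaves camera 1 residual degree of freedom and little power, so that result decides nothing about the lists. With processed signals Actb lay at -0.0013 and Gapdh at -0.063. With the mean of a gene's probes Gapdh lay at -0.10, where its probes disagree. With median centring Lyl1 lay at 0.15. The cause was not tested in the other cases. Of 1518 tested alternative values of the 127 other named genes, 1507 kept their direction and side of the threshold. Of 324 tested values of the lists 297 did, 13 changed side and 14 changed sign, 8 of these with median centring, all in lists that had not passed. Of the values from 1 array, 254 of 254 for genes and 53 of 54 for lists kept their direction. Most named genes were picked by their values on these same 2 arrays, so the count for genes decides nothing. Signals near background limit the folds of dim genes, which the offset shrinks.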

Other observations

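The tests on a common factor, on Pycard and on erythroid genes were chosen only after the result was seen, and so was the rule that leaves the common factor undecided when the filter takes out many members of a list. Among lincRNA intervals on the array, 2369 were measured, of which 645 rose and 540 fell, against 3386 and 5357 of 12881 protein-coding genes. At least 2-fold on both arrays in 1 direction were 2.36% of the intervals and 11.4% of the protein-coding genes, but the intervals were dimmer (median log2 signal 7.09 against 10.002), which shrinks their folds. The intervals named here were chosen after their values were seen. The most lowered lay on chromosome 6 from 4841700 to 4847400 on the reverse strand (17.4-fold lower), and another on chromosome 6 from 40693617 to 40720167 was 12.1-fold lower. The ESlncRNA interval was the only one among the 10 largest changes that rose.

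Outside the fixed rule, Mt2 and Mt1, the metallothioneins that bind zinc and copper, were at 1.65 ± 0.072 and 1.09 ± 0.00073 (adjusted p = 9.56e-07 and 4.31e-06), against the fall of most hepatocyte markers. They were named after their values were seen, and erythroid cells also express them.

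Markers of other blood cells and of stroma were lower with ESlncRNA. Dye bias particular to 1 probe sequence is argued against as the main source of these falls. Probes of 1 gene with no overlap of at least 31 bases gave correlated values (r = 0.759 over 3574 pairs, and 0.736 over the 23 pairs of these markers). Both probes lay below 0 in 20 of those 23 pairs. Shorter overlaps were allowed, so a bias of a shared stretch stays open. A correction for base composition left the granulocyte median at -4.32, but it took out only 0.233% and 0.200% of the variance on the arrays of replicates 1 and 2, so its effect on the median decides nothing. One factor for all other cell types stays open: among members above background in both channels the granulocyte median (-4.72, 20 genes) lay -3.59 from the endothelial and stromal one (-1.13, 16 genes), but that filter takes out 12 of 28 endothelial and stromal members, among them those that fell to background, and progenitors may express others. Fewer myeloid cells in the ESlncRNA population is a candidate explanation, although lineage depletion and the GFP sort preceded RNA extraction. The pan-leukocyte panel fell (median -2.19, all 20 of 20 lower, from Inpp5d at -0.77 to Ncf4 at -3.84), but it was chosen after the arrays had been examined. Stem and progenitor genes fell too (median -1.50), so the panel's fall does not single out myeloid cells. Lower myeloid transcripts within progenitors stay open as a biological explanation, as does dye bias shared by all probes of a gene, since no dye swap was made.

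Pycard and most inflammasome genes were lower with ESlncRNA. Fewer myeloid cells in the ESlncRNA population and a lower level in each erythroid cell cannot be told apart for Pycard. Of the 20 genes of the pan-leukocyte panel 10 fell further than Pycard, but the panel's range takes in 95.5% of the 1610 genes at least 2-fold lower on both arrays, so this decides nothing.

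Erythroid genes were higher with ESlncRNA. One common rise from the loss of other cells cannot be told apart from separate changes of single genes: the SD between 62 erythroid membrane and heme genes was 12.5 times their median standard error, but that error holds only the noise between arrays of what may be the same RNA. More mature erythroid cells, with lower Cd34 and higher Hebp1, are a further candidate explanation that was not tested. Of the 33 late erythroid genes 22 rose and 6 fell, among them Pim1 at -0.88.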
